A study of Rattus norvegicus with 45 samples.

How the data were processed

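RNA from hippocampal regions CA1, CA3 and the dentate gyrus (DG) of 15 male F344xBN rats was measured on 45 Affymetrix RAE 230 2.0 arrays, 1 per region and animal, which cover 31099 probe sets. Per the labels, 9 animals fed ad libitum were middle-aged (ALMA, 18 months, 3 animals) or old (28 months) good or poor performers (ALO_GP and ALO_PP, 3 animals each). The other 6 were old good or poor performers kept on restricted food (CRO_GP and CRO_PP, 3 animals each). Restriction began at 14 weeks, passed through steps of 10% and 25%, and reached 40% at 17 weeks. The test behind the performance classes is not given in the sources used here.

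The authors deposited dChip signal values, model-based expression indices on a linear scale, in 1 table of the 27 ad libitum arrays, 1 table of the 36 old arrays and 1 table per region for diet, each with detection calls (other unit: present, absent or marginal per probe set and array). The dChip version, its background setting and its probe model are not given in the sources used here. The deposited description of the normalisation says that the age arrays were normalised per region and the diet arrays together, while the deposited tables are laid out in the reverse way, with 1 table for all age arrays and 1 per region for diet beside the table of all old arrays. The authors also deposited a second signal value for every array, called the value table below, on a linear scale with a trimmed mean of 150 on each array. Its software and scaling are not given in the sources used here. The deposited lists of changed probe sets hold mean signals per class, which were not used here, and an unadjusted parametric p-value of at most 0.001 and a signed fold (other units), which the authors computed and which were compared here for direction only. Median signals per array ran from 151.2 to 175.5 in the age table, from 153.1 to 187.6 in the diet table and from 29.63 to 45.48 in the value table. Present calls covered 58.85% to 67.38% of probe sets per array. The small number of arrays per group limits the precision of every value.

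Each dChip signal was raised by a pseudocount of 16 and taken to log2. Probe sets with a mean above the 40th percentile were kept, which left 18625 per table, and limma 3.58.1 under R 4.3.3 was used with a two-sided threshold of 0.05 on p adjusted by Benjamini and Hochberg over all of them. Age (old minus middle-aged, 6 against 3 animals), diet (restricted minus ad libitum, 6 against 6) and performance (poor minus good, 6 against 6, with diet in the model) were tested per region and on the mean of the 3 regions of each animal. Regions were compared in the 9 ad libitum animals with the animal as a block. Age by region and diet by region were tested with the animal as a random block (consensus correlations 0.0286 and 0.0897), and diet by performance on the animals' means. Single values were compared by exact two-sided permutation tests. Title replicate numbers do not pair animals of different classes: residuals of arrays with the same number correlated by -0.018 on average over 84 pairs, against 0.01 over 186 pairs with other numbers.

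Probe sets took gene symbols from the deposited annotation columns, updated through RefSeq gene records: 18086 had 1 symbol, 990 several and 11966 none, and 57 were controls. A gene stands in the text by its brightest probe set. The rule for named genes took, per comparison, the 5 largest increases and the 5 largest decreases past the threshold in which every animal of the smaller group lay on the same side of the other group's mean. It added up to 4 members of smallest p from each gene list, and the region markers for regions. Where no gene passed it took the 3 of smallest p in each direction. A part of the genes so chosen is named here, picked after their values were seen. The comparisons, this rule, the 29 gene lists and the first set of other settings were chosen before the data were examined.

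The lists were tested with limma's camera at an inter-gene correlation preset to 0.01 and adjusted over the lists of a comparison, and members were also adjusted over the list alone. They were antigen presentation (MHC), microglia, complement, interferon response, astrocyte, oligodendrocyte and myelin, endothelial and mural, choroid plexus, meninges and fibroblast, blood, interneuron, CA1 pyramidal, CA3 pyramidal and dentate granule markers, adult neurogenesis, immediate early genes, glutamate receptors, GABA receptors, calcium signalling, synaptic vesicle, oxidative phosphorylation, ribosomal protein, proteasome, chaperones, antioxidant and detoxification, cholesterol synthesis, glucocorticoid response, metabolism of insulin, fasting and ketones, and circadian clock. In age CA1 the members that rose, over all tested, were 2 of 18 for oligodendrocyte and myelin, 4 of 14 for endothelial and mural, 2 of 12 for meninges and fibroblast, 0 of 5 for choroid plexus, 0 of 2 for blood, 2 of 16 for interneuron, 1 of 10 for CA1 pyramidal, 1 of 13 for CA3 pyramidal, 2 of 11 for dentate granule, 3 of 10 for adult neurogenesis, 0 of 11 for GABA receptors, 3 of 35 for calcium signalling, 6 of 20 for synaptic vesicle and 3 of 18 for glucocorticoid response, with none that fell. Lists with members in both directions there were immediate early genes (7 rose and 1 fell of 21), glutamate receptors (4 and 1 of 16), oxidative phosphorylation (15 and 2 of 62), ribosomal protein (11 and 1 of 63), proteasome (6 and 2 of 32), chaperones (11 and 1 of 37), cholesterol synthesis (1 and 2 of 23), metabolism of insulin, fasting and ketones (10 and 1 of 32) and circadian clock (4 and 1 of 13). None of these lists passed the camera test in age CA1, where adjusted p ran from 0.3 to 0.968. Blood had too few members for that test. Camera compares a list with all other genes, and in age CA1 its direction was down while median and mean were above 0 for CA1 pyramidal and dentate granule markers, adult neurogenesis, GABA receptors, calcium signalling, proteasome, chaperones and glucocorticoid response. Medians and means differed in sign for CA3 pyramidal markers (-0.03 and 0.012) and cholesterol synthesis (0.039 and -0.034).

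The calls were tested on simulated data with 18625 probe sets, of which 100 were changed at each size, and with noise drawn independently per probe set and array. At a log2 size of 1 and of 0.5 the tests recovered 94 and 45 for age CA1, 92 and 54 for diet DG, 87 and 52 for performance CA1, 99 and 89 for CA3 against CA1, and 80 and 45 for age by region. A simulated list raised by 0.4 was the only 1 of 28 lists called. The other settings chosen before seeing the data were a pseudocount of 64, no filter, the value table, a block of title numbers or none, the regional dChip tables, performance as a covariate, leaving out arrays with ambiguous labels, and leaving out each array or animal. Those added after seeing the data were the array sets described with the results, the arrays the authors marked, ALO_GP replicate 1, and the overlap of calls between the value table and the dChip signals. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No array was left out. The CA3 array of ALMA replicate 2 carries the code of another animal in its description and was kept as the animal of that replicate number, and the DG array of CRO_GP replicate 2 is described as a poor performer but was kept as titled.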

Results

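The data are signals of 45 arrays from hippocampal CA1, CA3 and DG of 15 rats, in 15 groups of 3 arrays: 5 classes of 3 animals in 3 regions. The classes are middle-aged rats fed ad libitum (ALMA) and old rats that were fed ad libitum or restricted, each split into good and poor performers (ALO_GP, ALO_PP, CRO_GP, CRO_PP). The series was made to follow hippocampal gene expression with age and with restriction. Values are log2 differences of dChip signals with their SE, and the same difference in the value table is given beside genes where it decides the reading.

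Poly-A control transcripts, bacterial RNAs added to a sample before labelling, part the arrays into 3 sets that follow the groups. DapX had a median signal of 628.7 in set A (9 arrays, 533.9 to 700), 189.2 in set B (22 arrays, 147.5 to 283.2) and 4.408 in set C (14 arrays, 0.4954 to 12.61). Set A holds all middle-aged arrays, and all 18 old ad libitum arrays lie in set B. Of the restricted arrays, set C holds the 3 of poor performers in CA1, 5 of 6 in CA3 and 6 of 6 in DG. Age therefore cannot be told apart from the step between sets A and B, nor diet in DG from the step between B and C. Diet in CA1 can be examined within set B, with 3 restricted and 6 ad libitum arrays. These restricted arrays are all from good performers and the ad libitum ones from both classes, so performance is not balanced there.

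**Figure D1:**
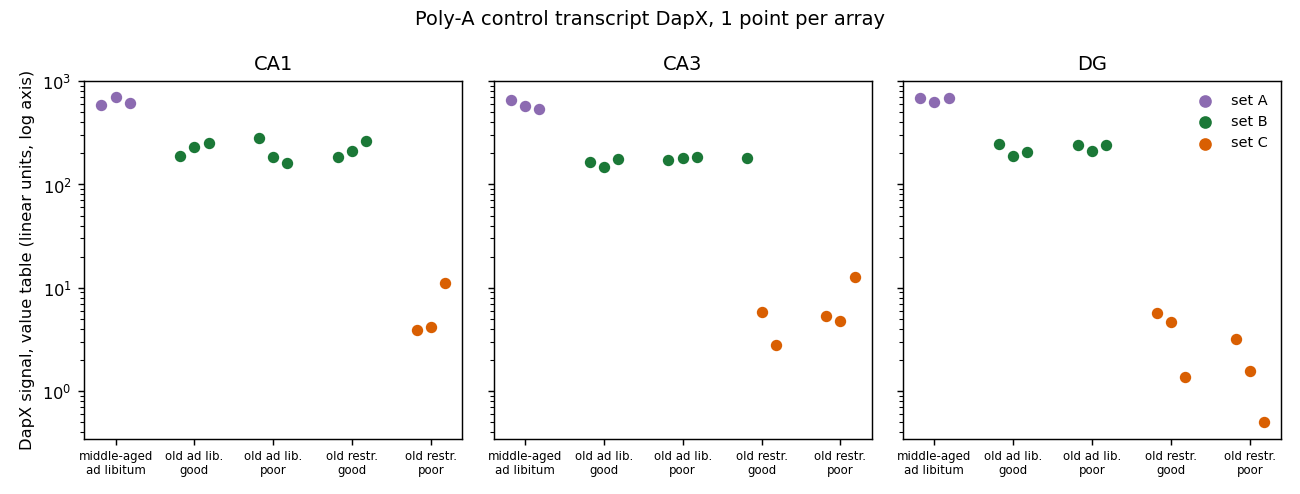
Signal of the poly-A control DapX in the value table (linear units, log axis) for each array, by class and region, coloured by array set. The middle-aged arrays lie from 533.9 to 700, the old ad libitum arrays from 147.5 to 283.2, and the restricted arrays of set C at or below 12.61.

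In CA1 of old rats, genes of antigen presentation were higher than in middle-aged rats (6 and 3 animals), with a median of 0.77 over the list. RT1-Db1, a class II MHC chain, rose 6.80-fold (log2 2.77 ± 0.53), and RT1-Bb rose by 2.75 ± 0.484 and RT1-Ba by 2.30 ± 0.419. Cd74, the invariant chain that guides class II molecules, rose 4.85-fold (2.28 ± 0.371), and Tap2, a peptide transporter for class I, rose 3.95-fold (1.98 ± 0.264). Of the 15 tested genes of that list 12 rose, 0 fell and 3 did not pass (14 rose adjusted over the list alone). Camera gave adjusted p = 0.0192 in the dChip signals and 0.00136 in the value table, and adjusted p = 0.981 with an estimated correlation. Differences in the value table had the same direction, at 2.31 for RT1-Db1, 2.26 for RT1-Bb, 2.18 for RT1-Ba, 2.21 for Cd74 and 1.07 for Tap2. The list's mean was higher in every old array than in every middle-aged CA1 array (difference 1.24, exact permutation p = 0.0119, the smallest that 84 splits can give). Without ALO_GP replicate 1, whose arrays were the highest of all, the difference was 1.09 (exact p = 0.0179).

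Single genes of other immune and glial lists were higher in old CA1 as well, but none of these lists passed camera in dChip signals with all animals. Of all 9535 genes tested there 2364 rose. Microglial genes rose in 7 of 17 cases, and 13 rose adjusted over the list alone. They included Trem2, a lipid-sensing receptor of microglia (1.00 ± 0.0772, 2.00-fold), its adaptor Tyrobp (1.31 ± 0.247) and Csf1r, the receptor for a microglial growth factor (0.69 ± 0.122). Camera gave adjusted p = 0.0524 for microglia in dChip signals (0.00412 without ALO_GP replicate 1) and 0.00693 in the value table, and adjusted p = 0.981 with an estimated correlation. In complement 3 of 11 rose (5 adjusted over the list alone, camera 0.554): Serping1, the C1 inhibitor (1.73 ± 0.294), C1qa (1.00 ± 0.297) and C3 (1.03 ± 0.314). C1qa did not pass without the filter (0.0522), without ALMA replicates 1, 2 or 3 (0.0616, 0.0718 and 0.104) or without ALO_PP replicate 2 (0.0514). C3 did not pass without the filter (0.0568), ALMA replicates 2 or 3 (0.0961 and 0.148), ALO_GP replicate 2 (0.0532) or ALO_PP replicate 2 (0.0577). Interferon response genes rose in 11 of 20 cases (11 adjusted over the list alone, camera 0.0998), among them Ifitm3 (0.84 ± 0.136), Irf1 and Stat2, of which the latter pair did not pass in the value table. Among astrocyte genes 8 of 17 rose (11 adjusted over the list alone, camera 0.174), with Gfap, the astrocyte filament protein, at 0.31 ± 0.0735 (adjusted p = 0.062 without ALMA replicate 3) and the gap junction gene Gjb6 at 0.33 ± 0.0606. In the antioxidant list 11 of 28 rose (11 adjusted over the list alone, camera 0.113), with Sod3, an extracellular superoxide dismutase, at 1.20 ± 0.125 and the metal-binding Mt1 at 1.03 ± 0.159. Arc, an activity-induced gene of synapses, rose by 0.82 ± 0.184. Medians of cell types that a dissection can add were 0.24 for meninges and fibroblast, -0.12 for choroid plexus and 0.26 for endothelial and mural genes, and 0.86 for the 2 tested blood genes, neither of them past the threshold.

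Beside the antigen presentation genes given above, the largest changes in old CA1 differed between the signals. Eml2, a microtubule-binding protein gene, rose by 2.43 ± 0.218 (1.25 in the value table) and Pck2, mitochondrial PEP carboxykinase, by 2.83 ± 0.0811 (0.39 in the value table). Tmc4, a channel-like membrane protein gene, fell by 2.71 ± 0.12 and by 1.61 in the value table, although it was called present on 0 of 9 arrays. Rpia (log2 -3.62 ± 0.106), Hmga2 (7.99-fold lower, SE 0.21), LOC679931 (-2.84 ± 0.0985) and Hcn4 (-2.50 ± 0.0968), also present on 0 of 9 arrays, fell past the threshold in dChip signals only. Their differences in the value table were -0.35, 0.08, -0.03 and -0.02, none past the threshold there. Slc17a7, a vesicular glutamate transporter (0.66 ± 0.11), and Igf1 (0.63 ± 0.134) rose in dChip signals and did not pass in the value table, at 0.18 and 0.37.

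In age CA1, 5149 probe sets passed limma's threshold, 3814 higher and 1335 lower, and 7381 had an unadjusted p under 0.05. The value table of the same arrays gave 3372, 2006 higher and 1366 lower, and 2035 were called in both with the same direction. Of the 196 probe sets lower by over 2-fold the value table called 26, with a median difference of 0.0056 against -1.5 in dChip signals. Of the 152 higher by over 2-fold it called 121, with medians of 0.86 and 1.22. Without ALMA replicate 3 the dChip count was 3422.

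**Figure D2:**
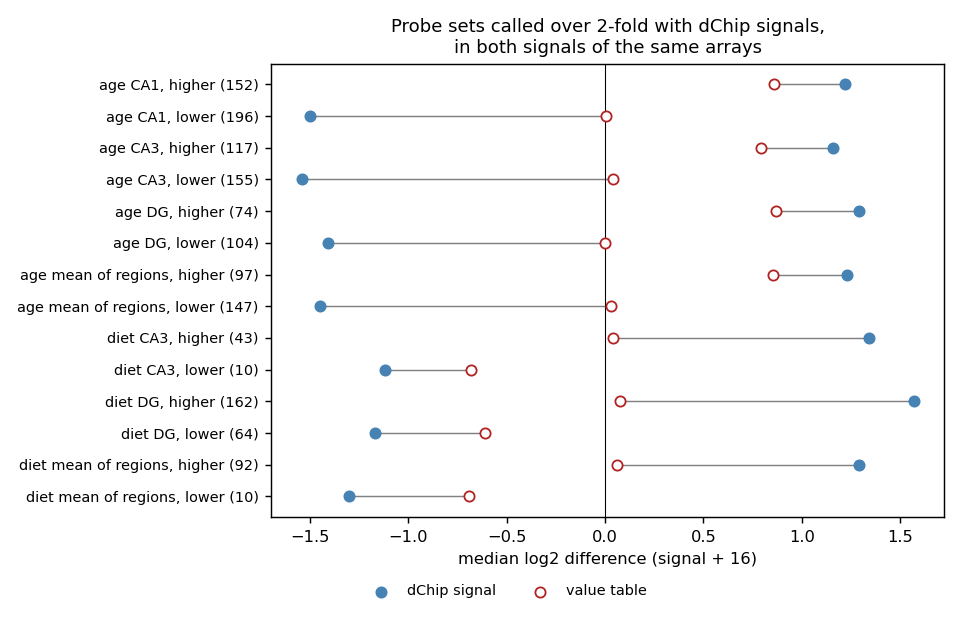
Median log2 difference of the probe sets that changed over 2-fold in dChip signals (filled points), and of the same probe sets and arrays in the value table (open points), with their number in brackets. Rises with age and falls with restriction kept their sign, while the medians of falls with age (0.0018 to 0.040) and of rises with restriction (0.040 to 0.078) lay near 0 in the value table.

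In CA3 of old rats the antigen presentation and microglial lists passed the camera test, while complement (0.556) and interferon response (0.138) did not. Antigen presentation genes rose in 7 of 15 cases (10 adjusted over the list alone, camera 0.0391), including Tap2 (1.90 ± 0.185), and microglial genes in 5 of 17 (5 adjusted over the list alone, camera 0.0494). RT1-Bb rose by 1.64 ± 0.466 and did not pass in the value table (1.49, adjusted p = 0.0541), without the filter (0.0607), with a block of title numbers (0.0515) or without ALMA replicate 1, 2 or 3 (0.107, 0.0651 and 0.1), ALO_GP replicate 3 (0.0594) or ALO_PP replicates 3 or 4 (0.05 and 0.0549). The adjusted p was 0.917 for both with an estimated correlation. Eml2 rose by 2.42 ± 0.247 and Erf, a repressor of ETS target genes, by 1.69 ± 0.208, with 0.97 and 1.26 in the value table. Ccdc65 (2.20 ± 0.0747) and Hmga2 (-2.67 ± 0.35) passed in dChip signals only, at 0.04 and 0.05 in the value table, and Rpia fell by 3.19 ± 0.12 (value table at -0.76). In all 3729 probe sets passed, 2825 higher and 904 lower, against 2772 in the value table (1833 and 939), with 1523 in both. Without the CA3 array of ALMA replicate 2, which carries a repeated animal code, 2384 passed, and without that of replicate 3, 2316. Medians of the meninges and the choroid plexus lists in CA3 were -0.18 and -0.54 (camera 0.076 for both), and that of the 2 blood genes 0.59. Of the markers of neighbouring regions, dentate granule genes rose in 3 of 11 cases (median 0.35, camera 0.247) and CA1 genes in 1 of 10 (median 0.05, camera 0.804).

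In DG of old rats antigen presentation genes rose in 4 of 15 cases (10 adjusted over the list alone, camera 0.0153), with Tap2 at 1.72 ± 0.383 (adjusted p = 0.0867, 0.0722 and 0.0849 without ALMA replicates 1, 2 and 3, and 0.0501 without ALO_GP replicate 3) and RT1-Bb at 2.00 ± 0.51 (1.61 in the value table, adjusted p from 0.0826 to 0.144 without single ALMA replicates, from 0.0528 to 0.0649 without single ALO_PP replicates and 0.063 without the filter), and microglial genes in 3 of 17 (5 adjusted over the list alone, camera 0.0239). Antioxidant genes rose in 7 and fell in 1 of 28 cases (12 and 1 adjusted over the list alone, camera 0.0153), and those of oxidative phosphorylation, the mitochondrial chain that makes ATP, in 13 and 1 of 62 (17 and 1 adjusted over the list alone, camera 0.0239). Ribosomal protein genes rose in 6 of 63 (6 adjusted over the list alone, camera 0.0367), and the value table gave 0.915 in the other direction for that list. In calcium signalling 0 of 35 passed while camera gave 0.0448 downward. Without ALO_GP replicate 1, whose DG array was high in meninges genes, camera gave 0.0906 for ribosomal proteins, 0.161 for calcium signalling, and 0.0376 downward for meninges and fibroblast (median -0.36, and 0.09 with that animal). The adjusted p of each of these lists was 0.971 with an estimated correlation. Eml2 rose by 2.47 ± 0.377 (1.61 in the value table). Ccdc65 (2.26 ± 0.0624), Hmga2 (-2.67 ± 0.295), Zfp512b (-1.92 ± 0.167) and S1pr2, a receptor for sphingosine phosphate (-1.83 ± 0.155), passed in dChip signals only, and S1pr2 had the opposite sign in the value table (0.34). In all 1917 probe sets passed, 1527 higher and 390 lower, against 1227 in the value table, with 662 in both. The dChip count was 690, 842 and 1115 without ALMA replicates 1, 2 and 3.

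Over the mean of the 3 regions 7478 probe sets passed, 5263 higher and 2215 lower, against 6644 in the value table (3831 and 2813), with 3985 in both. RT1-Db1 (2.14 ± 0.466, 1.84 in the value table), RT1-Bb (2.13 ± 0.385, 1.78) and Eml2 (2.44 ± 0.133, 1.28) rose in both signals. Rpia fell by 3.30 ± 0.0614 and by 0.51 in the value table, while Ccdc65 rose by 2.22 ± 0.052 in dChip signals and stood at 0.07 in the value table. Antigen presentation genes rose in 12 of 15 cases (14 adjusted over the list alone), with a camera adjusted p of 0.0857 in dChip signals (0.00282 without ALO_GP replicate 1) and 0.0124 in the value table, and adjusted p = 0.994 with an estimated correlation. All middle-aged arrays lie in set A and all old ones in set B, as with each result on age.

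The difference with age differed between regions for 4 probe sets by limma's interaction test (749 at an unadjusted p under 0.05), named here after their values were seen. Pck2 rose by 2.83 ± 0.0811 in CA1, 1.03 ± 0.128 in CA3 and 0.49 ± 0.147 in DG (interaction adjusted p = 1.06e-07). Tmc4 differed by -2.71 ± 0.12, -2.29 ± 0.0872 and -1.39 ± 0.151 (0.00373), and Hook3, a motor adaptor gene, by -0.38 ± 0.0826, 0.72 ± 0.161 and -0.13 ± 0.0995 (0.0245). The other one has no symbol (0.00195). The value table gave 0 such probe sets, and the dChip count was 8, 10 and 51 without the animals of ALMA replicates 1, 2 and 3.

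In DG, restricted old rats had lower signals of antigen presentation and microglial genes than old rats fed ad libitum (6 animals each). RT1-Db1 fell 3.35-fold (log2 -1.75 ± 0.465, value table at -1.29), and Tap2 fell by 1.60 ± 0.287 (value table at -1.01). Antigen presentation genes fell in 6 of 15 cases (6 adjusted over the list alone, camera 0.0128) and microglial genes in 5 of 17 (6 adjusted over the list alone, camera 0.0234), among them Cd53, a tetraspanin of leukocytes (-0.84 ± 0.165, value table at -0.61). Trem2 (-0.58 ± 0.142) and C3 (-0.75 ± 0.236) fell in dChip signals and did not pass in the value table. C3 also did not pass without ALO_GP replicate 1, ALO_PP replicate 1, CRO_GP replicates 2 or 3, or CRO_PP replicates 1 or 3 (0.0521 to 0.0642). In complement 3 of 11 fell (3 adjusted over the list alone, camera 0.39). Interferon genes fell in 6 and rose in 1 of 20 (7 and 1 adjusted over the list alone, camera 0.0965): Mx2 (-0.70 ± 0.138) and Ifit1 (0.77 ± 0.148, present on 0 of 12 arrays) did not pass in the value table. Without ALO_GP replicate 1 the difference of the antigen presentation mean in DG went from -0.655 to -0.486 (exact p = 0.00866 and 0.0173), and the microglial camera test to 0.0605. Both lists had an adjusted p of 0.973 with an estimated correlation. All 6 restricted DG arrays lie in set C and all 6 ad libitum ones in set B, and this holds for each gene of DG and diet.

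Synaptic vesicle and cholesterol synthesis lists were higher in restricted DG, and the ribosomal protein list lower. Glutamate and GABA receptor genes went both ways, with 2 that rose and 3 that fell in each list (camera 0.826 and 0.825). Synaptic vesicle genes rose in 10 and fell in 1 of 20 cases (11 and 1 adjusted over the list alone, camera 0.000155, value table at 0.0338). Slc17a7, which loads glutamate into vesicles, rose 2.02-fold (1.02 ± 0.165, value table at 0.75), and the vesicle fusion gene Vamp2 (0.38 ± 0.0511) and the vesicle protein Syp (0.32 ± 0.0526) rose in both signals. Ribosomal protein genes fell in 22 of 63 cases (23 adjusted over the list alone, camera 8.27e-05, value table at 2.88e-21), with Rpl29 at -0.47 ± 0.0581 (value table at -0.53) and Rps25 at -0.50 ± 0.0701, which the value table did not call. Calcium signalling genes rose in 8 and fell in 1 of 35 (8 and 1 adjusted over the list alone, camera 0.0178). Cholesterol synthesis genes rose in 6 and fell in 1 of 23 (6 and 1 adjusted over the list alone, camera 0.0394, value table at 0.0982). Sqle, squalene epoxidase, rose by 0.23 ± 0.041 (value table at 0.30), while Lss (1.03 ± 0.17) did not pass in the value table. Igf1r, the receptor for IGF-1, rose by 0.52 ± 0.0648 (value table at 0.41). Igf1 itself fell by 0.67 ± 0.181, with the same direction but no call in the value table (-0.38, limma adjusted p = 0.073). Without ALO_GP replicate 1 camera gave 0.0605 for both calcium signalling and cholesterol synthesis. All of these lists had an adjusted p of 0.973 with an estimated correlation. Between the restricted DG arrays the mean of synaptic vesicle genes was lowest in CRO_PP replicate 1, at 11.856 against 12 to 12.018.

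For diet in DG 5914 probe sets passed, 2306 higher and 3608 lower, and 226 changed over 2-fold. The value table gave 3846 (2166 and 1680), and 2212 were called in both, 1106 in each direction. Of the 162 probe sets higher by over 2-fold, 41 were called in the value table (medians 1.57 and 0.078), and of the 64 lower by over 2-fold, 44 (medians -1.17 and -0.61). Of the largest rises, Gpx6 (3.82 ± 0.312, value table at 0.05, present on 0 of 12 arrays) and Polg (3.32 ± 0.279, value table at -0.09, present on 1) did not pass in the value table. Nccrp1 (3.20 ± 0.361) passed there at 0.65 (limma adjusted p = 0.0159). In the regional dChip table of the same 12 arrays Nccrp1 was at 0.57 and did not pass (adjusted p = 0.133). Gpx6 in ALO_GP DG arrays read 369 ± 149 (SD, n = 3) in the diet table, 4.27 ± 3.27 in the age table and 1.79 ± 1.79 in the value table. Over the 18 old ad libitum arrays that both dChip tables hold, 283 of 18166 probe sets were shifted by over 2-fold between them. Ccdc65 fell by 2.31 ± 0.0817 (value table at -0.05), and Eml2 by 1.53 ± 0.278 (value table at -0.60).

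In CA3, synaptic vesicle genes were also higher and ribosomal protein genes lower in restricted rats. These are the same animals as in DG, and all but 1 of the restricted CA3 arrays lie in set C. Diet in CA3 therefore cannot be told apart from the step between sets B and C. Synaptic vesicle genes rose in 3 of 20 cases (3 adjusted over the list alone, camera 0.0103, value table at 0.0616), with Vamp2 at 0.31 ± 0.0543 and Syp at 0.28 ± 0.0625 (value table at 0.36, adjusted p = 0.0662, and 0.0503 without CRO_PP replicate 2). Ribosomal protein genes fell in 9 and rose in 1 of 63 (12 and 1 adjusted over the list alone, camera 0.000308, value table at 2.65e-10), with Rpl29 at -0.51 ± 0.0834 and Rps25 at -0.46 ± 0.0961 (not past in the value table). Cholesterol synthesis genes rose in 4 of 23 (5 rose and 1 fell adjusted over the list alone, camera 0.0214, value table at 0.131), with Mvk at 0.33 ± 0.0592 (not past in the value table). Igf1r rose 1.67-fold (0.74 ± 0.0694) and Pnma8b fell 2.41-fold (-1.27 ± 0.248, value table at -1.20). Microglial genes fell in 2 of 17 cases (3 adjusted over the list alone, camera 0.0185): Cd53 (-0.76 ± 0.157, not past in the value table) and Trem2 (-0.44 ± 0.117, not past without the filter, at 0.0686, or without ALO_GP replicates 1, 2 or 3, ALO_PP 3 or 4, CRO_GP 2 or 3 or CRO_PP 2 or 3, at 0.0504 to 0.0869). Antigen presentation genes passed in 0 of 15 (0 adjusted over the list alone) with a camera adjusted p of 0.00725 downward, and interferon genes rose in 1 of 20 with 0.0444 downward (0.178 without ALO_GP replicate 1). The adjusted p was 0.788 for each of these lists with an estimated correlation.

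Region markers also differed with diet in CA3, whose old ad libitum arrays enter the comparison with age as well. With age, dentate granule markers rose there in 3 of 11 cases (median 0.353, camera 0.247). Whether the shared arrays account for both was not tested. With diet, dentate granule markers fell in 3 of 11 cases (4 adjusted over the list alone, camera 0.0308). Among them were the calcium buffer Calb1 at -0.65 ± 0.163 (not past in the value table, at 0.0519, without the filter, at 0.0558, or without ALO_GP replicates 2 or 3, ALO_PP 2 or 3, CRO_GP 1 or 3 or CRO_PP 2, at 0.0513 to 0.0728) and Pde1a at -0.53 ± 0.143 (value table at -0.37). CA1 markers fell in 2 of 10 (4 adjusted over the list alone, camera 0.059, and 0.0278 without ALO_GP replicate 1), with Man1a1 at -0.71 ± 0.145 (value table at -0.73). Pde1a did not pass without the filter (0.0741) or without ALO_GP replicates 1, 2 or 3, ALO_PP 2 or 3, CRO_GP 1 or 3 or CRO_PP 2 or 3 (0.0545 to 0.09). CA3 markers rose in 1 and fell in 1 of 13 (1 and 1 adjusted over the list alone, camera 0.0125 upward), with Spock1 at 0.53 ± 0.124 (value table at 0.31, adjusted p = 0.148, and 0.0503 to 0.0559 without ALO_GP replicate 2, ALO_PP 2 or 3, CRO_GP 3 or CRO_PP 2 or 3), and oligodendrocyte genes passed in 0 of 18 (0 adjusted over the list alone, camera 0.0103 upward). The adjusted p of each was 0.788 with an estimated correlation. The largest changes, Fam193b (1.87 ± 0.4), Prlh (1.77 ± 0.362, present on 1 of 12 arrays) and Ccdc65 (-1.82 ± 0.287), did not pass in the value table. In the regional dChip table of the same 12 arrays Fam193b was at 0.18 (adjusted p = 0.219) and Prlh at 0.16 (0.787). In all 1570 probe sets passed, 547 higher and 1023 lower, against 1186 in the value table (710 and 476), with 521 in both. With the array set as a covariate or within set B, the diet difference rests on 1 restricted array, so the number of calls decides nothing there. In both, Igf1r stood at 0.681, Cd53 at -0.79 and Calb1 at -0.884, about as over all arrays or larger. Fam193b at 0.673, Pnma8b at -0.529 and Rpl29 at -0.322 were smaller. Prlh at 1.32 and Rps25 at -0.607 in both, and Ccdc65 at -1.5 with the covariate, kept much or all of theirs. None of these 3 passed in the value table, so a size kept there does not set apart genes that hold in both signals. Without the array of CRO_PP replicate 4 that the authors marked as an outlier (ratio of GAPDH 3' to 5' signal 6.078) 4848 passed. It was 808, 728 and 714 without ALO_GP replicates 1, 2 and 3, 832 and 891 without ALO_PP replicates 2 and 3, 747 without CRO_GP replicate 3, and 659 and 829 without CRO_PP replicates 2 and 3.

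In CA1, the antigen presentation, microglial and interferon lists were lower in restricted rats although few single genes passed. Rbm3, a cold-induced RNA-binding protein gene, rose by 0.58 ± 0.0618 (adjusted p = 0.0086, value table at 0.74), higher in 6 of 6 restricted animals (adjusted p = 0.0506 without ALO_PP replicate 3). Antigen presentation genes passed in 0 of 15 cases over all probe sets and 9 fell adjusted over the list alone (camera 3.16e-05, value table at 6.25e-05). For microglia these were 0 of 17 and 9 (camera 0.00024, value table at 5.16e-05), for interferon response 0 of 20 and 6 (0.00342), for chaperones, which help proteins fold, 0 of 37 and 1 (0.000688), for antioxidants 0 of 28 and 2 (0.00342) and for ribosomal proteins 0 of 63 and 0 (0.00199, value table at 0.656, and 0.0637 without ALO_GP replicate 1), all downward by camera. Complement did not pass (0 of 11, 3 fell adjusted over the list alone, camera 0.143). The adjusted p was 0.91 for ribosomal proteins and complement and 0.805 for the others with an estimated correlation. Within set B the mean of the antigen presentation genes was 9.43 ± 0.133 (SD) in 3 restricted and 10.1 ± 0.39 in 6 ad libitum CA1 arrays, a difference of -0.706 that no other of the 84 splits undercut (exact two-sided p = 0.0357). It was -0.685 in the value table (exact p = 0.0357) and -0.567 without ALO_GP replicate 1 (exact p = 0.0179). For microglia it was -0.582 (exact p = 0.0714). Camera within set B was also downward for meninges and fibroblast (median -0.15, 0.0347), oligodendrocyte and myelin (-0.15, 0.00204), astrocyte (-0.12, 0.00505) and complement genes (-0.45, 0.00332), each with an adjusted p of 0.518 with an estimated correlation. Without ALO_GP replicate 1 the complement median there was -0.255. Over all CA1 arrays the medians of meninges, choroid plexus and the 2 blood genes were -0.04, 0.21 and -0.72, and the blood genes stood at -0.97 in both CA3 and DG, none past the threshold.

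By limma 4 probe sets passed for diet in CA1, 2 higher and 2 lower, against 4463 at an unadjusted p under 0.05, and 2 of them have a symbol: Rbm3 and Pnlip, annotated as pancreatic lipase (-0.53 ± 0.0738, not past in the value table, with a pseudocount of 64, without the filter, with a block of title numbers, or without ALO_GP replicates 2 or 3, ALO_PP 1, 2 or 3, CRO_GP 3 or CRO_PP 1 or 2, at 0.0671 to 0.163). The value table gave 39 (30 higher and 9 lower), and 1 probe set was called in both. The set as a covariate left 0, in which Rbm3 kept its difference (0.58, adjusted p = 0.102), and 6 passed within set B. Performance as a covariate gave 513, and leaving out the array of CRO_PP replicate 3, which the authors marked (GAPDH ratio 7.644), gave 258. The count was 249 and 33 without CRO_GP replicates 1 and 2, 7 without ALO_GP replicate 1, 0 without ALO_PP replicate 3, 2 without ALO_PP replicate 1, and 1 without ALO_GP replicate 2, ALO_PP replicate 2, CRO_GP replicate 3 or CRO_PP replicates 1 or 2.

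**Figure D3:**
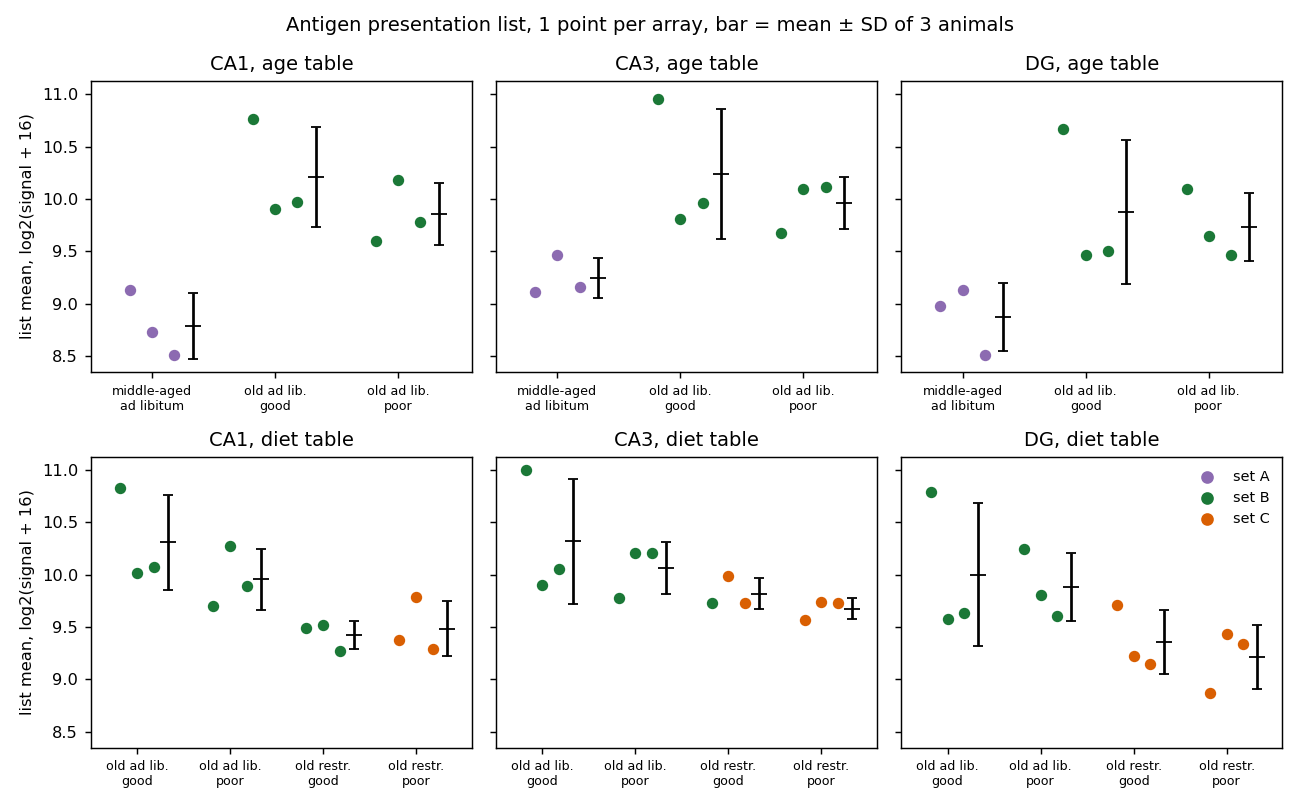
Mean log2 signal of the antigen presentation genes on each array by class and region, from the age table (top) and the diet table (bottom), coloured by array set, with bars for the mean ± SD of 3 animals. Middle-aged CA1 arrays lie from 8.51 to 9.13 and old ones from 9.60 to 10.76, and in the diet table the restricted CA1 arrays lie from 9.27 to 9.78.

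Over the mean of regions 5976 probe sets passed for diet, 2212 higher and 3764 lower, against 4785 in the value table (2624 and 2161), with 2733 in both. RT1-Db1 fell by 1.55 ± 0.343 (value table at -1.21) and Entpd1, an ATP-degrading enzyme of microglia and vessels, by 1.25 ± 0.198 (-0.44). Gpx6 (2.82 ± 0.273), Medag (2.11 ± 0.215) and Ccdc65 (-1.86 ± 0.178) did not pass in the value table. Antigen presentation genes fell in 10 of 15 cases (11 adjusted over the list alone, camera 0.00186), microglial genes in 8 (camera 0.0101), and ribosomal protein genes fell in 31 and rose in 2 of 63 (33 and 2 adjusted over the list alone, camera 7.42e-06). Synaptic vesicle genes rose in 5 and fell in 1 (camera 0.00691), and these lists had an adjusted p of 0.863 with an estimated correlation.

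Diet differed between regions for 5 probe sets by limma's interaction test (3776 at an unadjusted p under 0.05), named after their values were seen. Necab2, a neuronal calcium-binding protein gene, differed by -0.14 ± 0.083 in CA1, 0.19 ± 0.0662 in CA3 and 0.50 ± 0.0933 in DG, and Scn3a, a sodium channel gene, by -0.01 ± 0.0994, -0.78 ± 0.12 and -0.72 ± 0.0926 (adjusted p = 0.0313 each). Mbd6 differed by 0.29 ± 0.137, -0.45 ± 0.101 and -0.58 ± 0.102 (adjusted p = 0.0319), and the other 2 have no symbol. The share of restricted arrays in set C also differs between regions. The count was 0 in the value table and 27 with the set as a covariate. Without the animals of CRO_PP replicates 1, 2 and 3 in CA1 it was 390, 290 and 489, and without each of 8 other animals it was 3 or less.

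**Figure D4:**
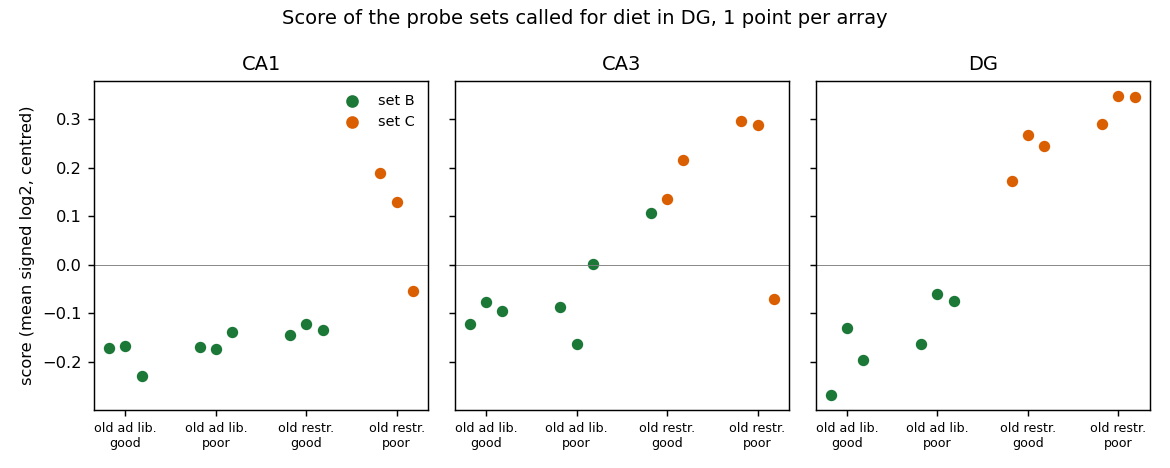
Mean signed log2 signal (centred) of the 5914 probe sets called for diet in DG, for each old array by class and region, coloured by array set. The CA1 means are -0.13 for restricted arrays of set B and 0.087 for those of set C, against -0.19 and -0.16 for the ad libitum classes.

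Poor and good performers, 6 animals each, differed at no probe set in a single region by limma. At an unadjusted p under 0.05 there were 3039 in CA1, 716 in CA3 and 2034 in DG. The genes of smallest p, given as not passing, included Nmb, a bombesin-like neuropeptide gene, in CA1 (-1.31 ± 0.217, adjusted p = 0.255), Plscr1 in CA1 (-0.51 ± 0.0884, 0.255), Sh3bgrl1 in CA3 (-0.36 ± 0.0645, 0.944), Sanbr in DG (-0.82 ± 0.138, 0.141) and B3gnt7 in DG (0.70 ± 0.126, 0.141). Over the mean of regions 4 probe sets passed, all lower in poor performers, and 1 has a symbol: Rnf125, a ubiquitin ligase gene (-0.43 ± 0.0527, adjusted p = 0.0259), which stood at 0.01 in the value table. That count was 0 in the value table, without a filter, with a block of title numbers and in ad libitum animals alone. Without single animals, numbered as in CA1, it was 22 without ALO_PP replicate 2, 14 without ALO_GP replicate 1, 7 without CRO_PP replicate 1 or 3, and 0 without ALO_GP replicate 2 or 3, ALO_PP replicate 1 or 3, CRO_GP replicate 1 or 3, or CRO_PP replicate 2. In restricted CA1 the performance classes lie in different array sets. Diet by performance gave 0 probe sets (1946 at an unadjusted p under 0.05).

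The regions differed in many genes within the 9 ad libitum animals, and the named ones passed in both signals. CA3 against CA1 had higher Patj, a cell polarity gene (2.04 ± 0.228), Nectin3, an adhesion gene (1.99 ± 0.225), and Cpne4 (1.88 ± 0.283), and lower Nxph3 (-2.46 ± 0.416), Adgrl2, a latrophilin receptor (-1.79 ± 0.299), and Rprm (-1.72 ± 0.244). DG against CA1 had higher Perp (1.29 ± 0.188) and Svep1 (1.26 ± 0.169) and lower Htr5b, a serotonin receptor (-2.24 ± 0.235), and Inhbb, an activin subunit (-1.76 ± 0.156). DG against CA3 had higher Perp (2.10 ± 0.188), the desmosome gene Dsp (1.95 ± 0.207) and the synapse organiser C1ql2 (1.89 ± 0.232), and lower Mlf1 (-3.09 ± 0.288), Tnnt1 (-2.70 ± 0.236) and Dusp5 (-1.97 ± 0.112), 9 of 9 animals in each case. Of 11 dentate granule markers, 8 were higher and 1 lower in DG than CA3 (median 1.12), and of 13 CA3 markers 9 were higher and 0 lower in CA3 than CA1 (median 0.33). Of 10 CA1 markers 6 were lower and 0 higher in CA3 than CA1 (median -0.45). In DG against CA1, 6 dentate granule markers were higher and 2 lower (median 0.611), but 6 CA3 markers were higher and 2 lower as well (median 0.272). Dentate granule markers were lower in CA3 than CA1 in 9 cases and higher in 0 (median -0.455). CA3 against CA1 gave 4163 probe sets (1647 higher), DG against CA1 3068 (1505 higher) and DG against CA3 6703 (3719 higher). The first was 2696 in the value table (1351 higher), 2644 without the animal block and 2773 without the animal of ALO_GP replicate 3.

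Differences with age and with diet were weakly opposed across probe sets. In the value table, where all arrays share 1 scale, the correlation across 18625 probe sets of both differences was -0.186 (probe sets are not independent replicates). The old ad libitum animals enter both differences, and simulated values without any effect gave -0.408 on average with a covariance of -0.0032, against -0.0085 in the data. With these animals split so that each served 1 difference, the median correlation over 20 splits was -0.123 (-0.182 to -0.0709). Set B is the set of the shared animals in both differences.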

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

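The tests of the split of arrays into sets, of the unspecific signal within restricted CA1 and of other groupings of the animals were chosen before their results were seen, while those of the counts without the marked arrays, of the bright probe sets, of the value table, of the microglial list within a set, of meninges, of blood and of the arrays without ALO_GP replicate 1 were chosen only after.

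Samples far from the others of their group of 6 stood out in 15 of 78 groups of list means and array measures, where chance gives about 1 in 20 independent groups and these share arrays and related lists. The ratio of GAPDH 3' to 5' signal was 7.644 in CA1 for CRO_PP replicate 3 (2.016 to 2.584 in the others) and 6.078 in CA3 for replicate 4 of that class (1.486 to 1.877), the same animal, whose arrays the authors marked as outliers. Its CA1 array also had the lowest mean of synaptic vesicle genes, 11.669 (11.807 to 11.875 in the others), and in DG that mean was lowest in CRO_PP replicate 1, at 11.856. ALO_GP replicate 1 had the highest means among old ad libitum animals for antigen presentation genes in CA3 (10.999), for microglia in CA1 (10.557) and CA3 (10.417), for complement in CA1 (10.86) and for interferon response in CA1 (9.2385), CA3 (9.4942) and DG (9.7566). Its DG array also stood out for meninges and fibroblast (11.388, others 8.2625 to 9.0312) and choroid plexus genes (10.898), as did CRO_GP replicate 2 in CA3 (9.4066 and 10.809). In the tests of a difference between regions, 4 probe sets passed for age and 5 for diet. In the control transcripts, which no comparison uses, DapX had a median of 628.7 in set A and 189.2 in set B, against 4.408 in set C.

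The number of probe sets called for diet rises with the share of restricted arrays in set C: 4 in CA1, 1570 in CA3 and 5914 in DG. Diet acting alike in CA1 and DG without a difference between sets is argued against, since restricted and ad libitum CA1 arrays of set B differed by 0.0405 in a score of the 5914 DG probe sets, a share of 0.0949 of the DG difference (exact p = 0.0952). The 2 arrays of degraded RNA are argued against as the account of the CA1 count, which was 258 without the marked array, but are a candidate source of the lower CA3 count, which was 4848 without it. Between restricted CA1 arrays of sets C and B the score differed by 0.222, a share of 0.52 (exact p = 0.1, the smallest that 3 against 3 allow, and 0.351 in the value table). Without the marked CA1 array the difference was 0.293, a share of 0.686. In CA3 the only restricted array of set B decides nothing (shares of 0.155 below set C and 0.463 above ad libitum), so a difference between sets cannot be told apart from diet. The restricted CA1 arrays of sets C and B also part poor from good performers, whose shares were 0.233 in restricted DG and 0.068 in ad libitum CA1, below the 0.52, so performance acting in restricted CA1 alone stays open, as does diet acting in DG and not in CA1. Across probe sets the DG diet difference correlated by 0.479 with that CA1 difference. It correlated by 0.468 with poor minus good in restricted DG, which lies in 1 set but shares arrays with it.

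Bright probe sets that were never called present often fell in old animals: 13 of 20 fell over 2-fold, a share of 65% against 0.636% for always-present ones of the same brightness (ratio 102), although 53 of the 147 probe sets that fell over 2-fold are bright and always present. Brightness was the mean over arrays of both ages, so probe sets high in middle-aged arrays alone could pass it. Such a choice favours falls with age, and the share of 65% therefore supports no cause. In restricted CA1 bright probe sets never called present differed more between the array sets, by a median of 1.26 against 0.172 (ratio 7.35), but the value table showed no such excess (0.11 against 0.176), so unspecific signal that follows the sets cannot be told apart from the way dChip summarised these probe sets. A lower RNA level in old animals is argued against as the account of the whole group, as 89 of all 147 were not lower in the value table, and 39 of the 57 with a median signal above 100 there were not. The median of the 147 was -1.45 in dChip signals and 0.033 in the value table, a ratio of -0.0226, while the 97 rises kept 0.86 of 1.23, so a candidate source is the dChip values of these probe sets alone. Single falls that hold in both, such as Tmc4, stay open to age and to the step between sets A and B.

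Genes of antigen presentation and microglia were higher in old and lower in restricted rats. For the diet part, the array sets alone are argued against for antigen presentation: within set B the CA1 difference was -0.706, a share of 1.04 of that over all CA1 arrays and below every other of the 84 splits (next -0.613), and -0.567 without ALO_GP replicate 1, lowest of 56. For microglia the share was 1.11, but another split reached -0.602 against -0.582, so chance or the sets cannot be excluded there. Meninges left on the tissue are argued against for age in CA3, where the median of those markers was a share of -0.247 of that of antigen presentation. In DG the shares without ALO_GP replicate 1 were -0.878 with age and -1.21 with diet. They argue against meninges for the remaining animals alone, as the DG array left out was itself high in meninges genes. Meninges cannot be told apart in CA1 (0.305 with age, 0.0612 with diet and 0.345 with diet within set B). Blood, with 2 tested genes, cannot be told apart in CA1 (shares of 1.12 with age, 1.22 with diet and 2.26 within set B). Nor can it in CA3 and DG, where its medians with age were 0.588 and 0.757. For age 0 array sets are shared by both ages, so the step between sets A and B stays open. All 3 restricted CA1 arrays of set B are from good performers, while the ad libitum ones are from both classes. An effect of restriction on antigen presentation genes in CA1 therefore stays open beside blood, meninges and performance, with age untested beyond this. The lists lost their call with an estimated correlation (0.518 within set B).

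For the counts of calls, chance can be excluded for age, with 1 of 84 splits as large in CA1 (5149, highest other 8), CA3 (3729, 0), DG (1917, 1) and the mean of regions (7478, 1). The same holds for diet, with 1 of 100 splits as large, in CA3 (1570, highest other 495), DG (5914, 2) and the mean of regions (5976, 2000). Chance can also be excluded for regions, with 1 of 100 each (4163, 3068 and 6703, highest other 928, 1623 and 201). Excluding chance does not part age from the step between sets A and B, or diet in CA3 and DG from that between B and C. Chance is left open for diet in CA1 (4, highest other 3), age by region (4, highest other 3), diet by region (5, highest other 3) and performance over the mean of regions (4, highest other 2). The limit set beforehand on the share of splits was met for these as well, with 1 split as large in each. Leaving them open is a further caution outside that rule. Counts this low lie close to the highest of the other splits. Without single arrays or animals they ran from 0 to 258, 3 to 51, 0 to 489 and 0 to 22. For performance in CA1, CA3 and DG (0, highest others 1, 0 and 1) and for diet by performance (0, highest other 93) all 100 splits are as large as a count of 0, so the splits say nothing there. The split with 93 calls, those with 495 and 2000 for diet, and those with 928 and 1623 for regions show that other groupings can give many calls. What these splits have in common was not tested.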

How the results depend on the processing

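The array set as a covariate, set B alone, leaving out arrays the authors marked, the diet CA1 lists in set B and performance in ad libitum animals alone were chosen after seeing the data, and for each value that moved the cause was not tested unless the setting leaves fewer arrays. The value table gave 3372 for age CA1, 1227 for age DG, 39 for diet CA1, 3846 for diet DG, 2696 for CA3 against CA1, and 0 for performance over the mean of regions, age by region and diet by region. In the value table, S1pr2 in DG with age turned to 0.343 (adjusted p = 0.224) and Rnf125 with performance to 0.0128 (0.945). Without the array with a repeated code age CA3 gave 2384. Diet CA1 gave 2 with a pseudocount of 64, without the filter or with a block of title numbers, 513 with performance as a covariate, 0 with the array set as a covariate and 258 without the marked array. Diet CA3 gave 852 without the filter, 0 with the set as a covariate, 5 within set B and 4848 without the marked array. With the set as a covariate and within set B, the CA3 difference rests on 1 restricted array, so those counts decide nothing. In both, Igf1r stood at 0.681, Cd53 at -0.79 and Calb1 at -0.884, about as over all arrays or larger. Fam193b at 0.673, Pnma8b at -0.529 and Rpl29 at -0.322 were smaller. Prlh at 1.32, Rps25 at -0.607 and, with the covariate, Ccdc65 at -1.5 kept much or all of theirs, although none passed in the value table. Performance over the mean of regions gave 0 without the filter, with a block of title numbers and in ad libitum animals alone. CA3 against CA1 gave 2644 with no animal block. Diet by region gave 8 without the filter, 0 without the animal block and 27 with the set as a covariate. The correlation of age and diet was -0.123 as the median of the split animals, -0.227 without the filter and -0.406 in dChip signals, each below 0 as the -0.186 given. Camera called 34 lists in age and diet, 0 with an estimated correlation, 33 with the mean of a gene's probe sets, 47 in the value table and 39 with diet CA1 taken within set B. The title-number block, which pairs no animals, moved only diet CA1 and performance over the mean of regions by over 1.5 times. Left out in turn, arrays or animals gave 3422 to 5308 for age CA1, 2316 to 4301 for age CA3, 690 to 2252 for age DG, 5702 to 7534 for its mean of regions, 0 to 258 for diet CA1, 659 to 4848 for diet CA3, 4483 to 5917 for diet DG and 4287 to 7650 for its mean. The ranges were 0 to 1, 0 and 0 to 2 for performance in CA1, CA3 and DG (the 1 and the 2 without ALO_GP replicate 2) and 0 to 22 for its mean, 2773 to 4721, 2241 to 3551 and 5465 to 7072 for the regions, 3 to 51 for age by region, 0 to 489 for diet by region and 0 to 3 for diet by performance (3 without the animal of CRO_PP replicate 3). Of 1805 values of named genes under alternatives, 1643 kept direction and side of the threshold, 160 lost the call, 0 gained it and 2 turned. Signal over background limits the dim and absent probe sets, but the signals differed at brighter ones too. Of the probe sets lower over 2-fold with age over the mean of regions, 57 had a median value table signal above 100, and 39 of these were not lower there.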

Other observations

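The tests of cold-induced and heat-shock genes were chosen only after their differences had been seen, and the comparisons with the deposited lists were planned as directions only.

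Rbm3, which passed for diet in CA1, and Cirbp, both cold-induced RNA-binding protein genes, were paired only because their differences had been seen, and their values are given without a test. Within set B, 3 restricted against 6 ad libitum CA1 arrays, Rbm3 was higher by 0.583 and Cirbp, which is not among the probe sets called for diet in CA1, by 0.396. The mean of 5 heat-shock genes (Hsph1, Hsp90aa1, Dnajb1, Dnaja1 and Hspd1), which help proteins fold, was lower by a difference of -0.085. Hspa8 was to be part of that mean but has no tested probe set with its symbol alone. Over all arrays Rbm3 differed by 0.581 in CA1, 0.38 in CA3 and 0.301 in DG, but Cirbp by 0.135 in CA3 and -0.0622 in DG. A lower body temperature of restricted animals may be a hypothesis for the CA1 values, which were seen before it was formed. It cannot be told apart from other effects of restriction, as no temperature is in these files and Cirbp did not differ alike in the other regions.

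Some probe sets differed widely between classes in dChip signals and little in the value table. Ccdc65 in CA1 read 92.2 ± 3.68 (SD, n = 3) in ALMA and 481 ± 9.62 in ALO_GP in the age table, 409 ± 118 in CRO_GP and 78.7 ± 8.5 in CRO_PP in the diet table, and from 50.9 to 67.3 in the value table in all of these. Between the dChip tables of the same arrays, Ccdc65 in CA1 of ALO_GP read 481 and 528 and Rpia 325 and 331, while Medag in DG of ALO_GP read 1780 ± 559 in the age table, 838 ± 238 in the diet table and 623 ± 217 in the value table. Rpia in CA1 read 4080 ± 501 in ALMA, 325 ± 38.7 in ALO_GP and 2070 ± 658 in CRO_PP in dChip signals, and 49.3 ± 16.6, 37.3 ± 5.02 and 52.8 ± 22.8 in the value table.

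The authors' lists name 2161, 1482, 920 and 4849 probe sets for age in CA1, CA3, DG and all regions, and 350, 1596, 2406 and 4203 for diet. Of those tested here, from 98.4% to 100% had the same direction. The lists were chosen by p from these same arrays, so that share is no independent support. For diet, 4 of 267 tested in CA1 and 691 of 1548 in CA3 passed the threshold used here, against 2157 of 2239 in DG. The CA3 array with a repeated code correlated by 0.16 with both other arrays of the animal it was kept as, and by -0.15 and -0.097 with those of the animal whose code it repeats. Pairs of arrays from 1 animal averaged 0.073 and pairs of other classes ran from -0.56 to 0.53, so these values do not identify the animal.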
